A study of Gasterosteus aculeatus with 17 samples.

How the data were processed

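RNA sequencing of gill tissue gave 1 library per fish for 17 three-spined sticklebacks, all males, from a lake and from a sea coast. Per the labels' protocols, polyadenylated RNA was purified on beads and libraries were made with a NEBNext mRNA kit. Per the submitters' processing notes, CASAVA 1.8.2 and TopHat2 2.1.0 were used upstream. The tool that counted reads, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The authors deposited whole-number counts per gene, not normalized, in a table of 22456 genes and 17 fish, with 0 columns of no sample, 0 duplicated IDs, 0 entries that name no gene and 664 genes at 0 in every fish.

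The counts have an unusual property that is a limit on every value. Among 17449 genes with a total over 200 counts, 4873 (27.9%) had counts that share a divisor of 2 or more in all fish, which in simulated Poisson counts occurred for 0 genes. What produced this is not given in the sources, and if such counts are multiples of a read number, their counting error is larger than the counts imply. The counts were tested as deposited, and again after division by the shared divisor. Reads shared between gene copies or overlapping genes, and strand, cannot be examined in the counts.

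Depth ranged from 6932688 to 28960967 counts per fish. Counting error is then small for abundant genes, and the spread between fish (biological coefficient of variation 23% to 39%) sets the precision. Replicate libraries of a group differed by far more than sampling noise (chi-square per degree of freedom 35.9 to 150.5 over 28 pairs), so no library was treated as a duplicate. Floors for a count of 0 use 3 counts over the group and cover counting error only.

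Groups were taken from the labels: marine fish in marine water (fish 2 to 5), marine fish in fresh water (fish 1 to 5), freshwater fish in marine water (fish 1 to 4) and freshwater fish in fresh water (fish 1, 2, 4 and 5). Fish of different groups share numbers but are separate wild animals, and no pairing was assumed. Genes were kept with edgeR's filterByExpr by group (minimum count 10), libraries scaled by TMM, and all 4 groups fitted together with edgeR 4.0.16 (glmQLFit and glmQLFTest, no covariates). The 5 pairwise comparisons and the interaction of population and water were tested, each with Benjamini-Hochberg adjustment at 0.05. Standard errors were obtained as the log2 fold change divided by the square root of its F value. CPM values use the same scaling, and principal components used log2 CPM with a prior count of 2. On counts simulated for the 18238 tested genes with 200 changed, 4-fold changes were recovered for 72.7% to 83.3% of genes in the pairwise comparisons, 2-fold changes for 28.4% to 40.3%, and 1.5-fold changes for 1.5% to 6%, with 3 to 7 false calls among 73 to 86. Simulated genes varied independently, so these rates leave out structure that real fish share across genes. Other splits of the real fish called up to 954 (marine fish), 1303 (own waters) and 1097 (interaction) genes. Simulation, thinning and drawn splits each used a single fixed random seed.

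The groups, the comparisons, the tests, most alternatives, the 31 gene lists and the rule for named genes were fixed before the data were examined. The rule asked for an adjusted p below 0.05, a gene symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups compared, then took the largest rises and falls. None of the 22456 IDs could be matched to the reference gene table (52177 genes of assembly fGasAcu3.hap1.1, 0 with an Ensembl ID). The symbol requirement was therefore dropped and the rule limited to the 2 largest rises and 2 largest falls, by ID. For the same reason none of the 31 lists (ion transport, stress, immune and cell type markers among them) could be tested, and whether known osmoregulatory genes changed is not answered here.

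Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling, no or a stricter low-count filter (5 CPM in 4 fish), DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, robust edgeR, only the groups compared, the fish number as a block, and each fish left out in turn. Added after seeing the data were thinning of every library to 6932688 counts ("at equal depth"), division by shared divisors, leaving out moved marine fish 1 and 2 together, and the overlaps, sign shares and list-alone counts between the water responses. Other scalings moved the median log2 change of all genes by -0.07 to 0.04. Up to 100 splits of the same fish, the real one included, were refitted for each count. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.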

Results

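Gill expression was measured by RNA sequencing of polyadenylated RNA from 17 wild three-spined sticklebacks (Gasterosteus aculeatus), a small fish with populations in the sea and in lakes. The gill is the main organ through which such fish take up or secrete salt. All fish were males in breeding dress, from a lake (freshwater fish) or from a sea coast (marine fish), and each library came from a separate individual. Marine fish were kept in marine water (4 fish) or moved to fresh water for 4 days (5 fish), and freshwater fish were kept in fresh water (4 fish) or moved to marine water for 4 days (4 fish). The kept fish were also held captive, so captivity was shared by kept and moved fish. The design asks how gill expression responds within days to a change in salinity, and how the 2 populations differ when water is the same. Total counts per library, rounded, were 18520000 ± 650000 in kept marine fish (SD, n = 4) and 10650000 ± 3440000 in moved marine fish (n = 5). They were 26370000 ± 1870000 in moved freshwater fish (n = 4) and 25890000 ± 2330000 in kept freshwater fish (n = 4). The lowest total was 6932688, in moved marine fish 2, so depth differed between populations and, among marine fish, with the water. Of 22456 genes listed, 18238 passed the low-count filter and were tested. The files do not pair the gene IDs with names, so genes are given by ID, with at most 2 that were higher and 2 that were lower per comparison.

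**Figure D1:**
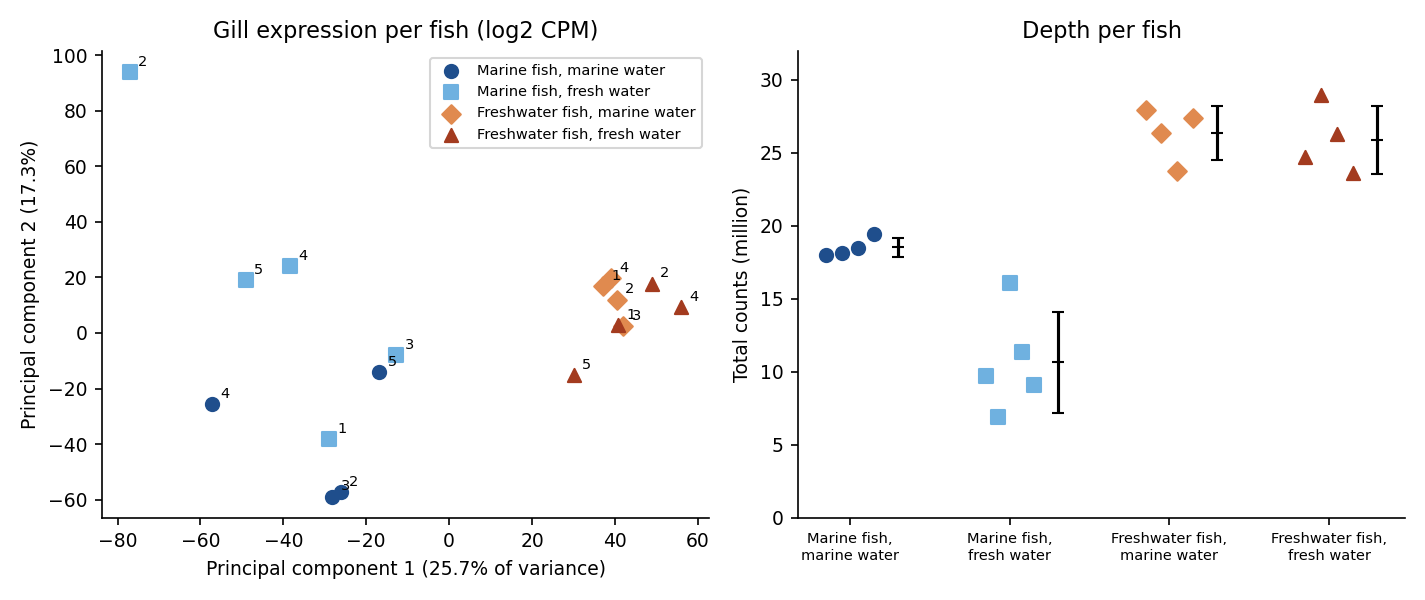
Left, each of the 17 fish on the first 2 principal components of log2 CPM (counts scaled to a common library total), numbered as in the labels; right, total counts per fish, with the group mean and SD beside the points. All 9 marine fish lie at or below -12.8 on the first component and all 8 freshwater fish at or above 30.1, and moved marine fish have the lowest totals.

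The fish separated by population before anything else. The first principal component held 25.7% of the variance and placed marine fish between -77 and -12.8 and freshwater fish between 30.1 and 56. The next component held 17.3% and was led by moved marine fish 2, at 93.9. The biological coefficient of variation was 30% in kept marine fish, 39% in moved marine fish, 23% in moved freshwater fish and 28% in kept freshwater fish. Moved marine fish 1 and 2 stood farthest from their group, with 942 and 1009 genes over 2 log2 units from the mean of the other fish, against 400 to 415 in moved marine fish 3, 4 and 5. At equal depth these were 641 and 772 (fish 1 and 2) against 405, 248 and 204 (fish 3, 4 and 5).

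Freshwater fish moved to marine water for 4 days were compared with freshwater fish kept in fresh water. In the moved fish far more genes were lower than higher: 115 genes were lower and 22 higher, with a median change of 1.5 log2 units. Marine water and being moved cannot be told apart in this comparison. Of the lowered genes 29 fell more than 4-fold, and of the raised genes 9 rose more than 4-fold. ENSGACG00000000206 went from 765 ± 369 CPM in fresh water (SD, n = 4) to 37.8 ± 11.5 CPM in marine water (n = 4), a log2 change of -4.34 (SE 0.79, edgeR adjusted p = 0.015). ENSGACG00000005001 went from 17.8 ± 9.07 to 0.965 ± 0.768 CPM, a log2 change of -4.20 (SE 0.62, edgeR adjusted p = 0.0032). In the other direction, ENSGACG00000000730 was near absent in fresh water, at 0.161 ± 0.121 CPM, and reached 6.41 ± 0.799 CPM in marine water, a log2 change of 5.31 (SE 0.37, edgeR adjusted p = 5.7e-07). ENSGACG00000007890, an abundant transcript, rose from 152 ± 106 to 1120 ± 155 CPM, a log2 change of 2.88 (SE 0.63, edgeR adjusted p = 0.043), and was past the threshold in 17 of 29 alternative analyses. The 137 genes are 0.8% of those tested, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. At an unadjusted p below 0.05 there were 1725. The values of kept and moved fish did not overlap for 136 of the 137 genes, and for 7.9% of all tested genes, where chance gives 2.86%. The count was 254 when only these 8 fish were fitted, 347 with DESeq2 and 627 with limma voom, and at equal depth it was 71. Without single fish it was 43, 45, 89 and 37 (moved fish 1, 2, 3 and 4), and 56, 63 and 85 (kept fish 1, 4 and 5).

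Marine fish moved to fresh water for 4 days were compared with marine fish kept in marine water. By edgeR with all fish, 262 genes rose and 262 fell, and the large changes were nearly all rises: 112 genes rose more than 4-fold and 3 fell more than 4-fold. ENSGACG00000004484 went from 57.4 ± 17 CPM in marine water (SD, n = 4) to 1490 ± 1990 CPM in fresh water (n = 5), a log2 change of 4.70 (SE 0.77, edgeR adjusted p = 0.015). ENSGACG00000000068 went from 5.82 ± 1.13 to 160 ± 244 CPM, a log2 change of 4.77 (SE 1.00, edgeR adjusted p = 0.028). These rises were uneven among the moved fish: fish 2 reached 4920 and 581 CPM for these genes, and over the 112 genes the median rise above the kept mean was 4.26 log2 units in fish 2 and 3.03 in fish 5, but 1.85, 1.21 and 0.70 in fish 1, 4 and 3. ENSGACG00000009233 went from 25.8 ± 10.5 to 7.18 ± 3.34 CPM (log2 change -1.83, SE 0.37, edgeR adjusted p = 0.025), and ENSGACG00000018249 from 10.2 ± 8.58 to 2.81 ± 0.512 CPM (log2 change -1.87, SE 0.45, edgeR adjusted p = 0.039).

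The 524 genes are 2.9% of those tested, and 4088 genes had an unadjusted p below 0.05. Values did not overlap for 328 of the 524, and for 5.5% of all tested genes, where chance gives 1.59%. This count was fragile. It fell to 0 by edgeR without kept marine fish 2, 3 or 4 (3234, 3122 and 3678 genes at an unadjusted p below 0.05), and to 0 when only the 9 marine fish were fitted (3107 at an unadjusted p below 0.05). It was 1221 without kept marine fish 5, 841 and 118 without moved marine fish 1 and 2, and 345 without moved marine fish 4. Leaving out freshwater fish, which set part of the shared spread, gave 348 and 333 (moved fish 1 and 2) and 331 (kept fish 1). With all fish, DESeq2 called 1733 genes and limma voom 244. At equal depth edgeR called 242. The even split of rises and falls did not hold either: the share that rose was 38.5% with limma voom, 58.8% with upper-quartile scaling, 63.6% at equal depth, and 65.5% and 79.7% without moved marine fish 1 and 4. The 4 named genes kept their direction in every alternative, which their choice for groups without overlap made nearly certain. They passed the threshold in 14 to 24 of 28 or 29.

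**Figure D2:**
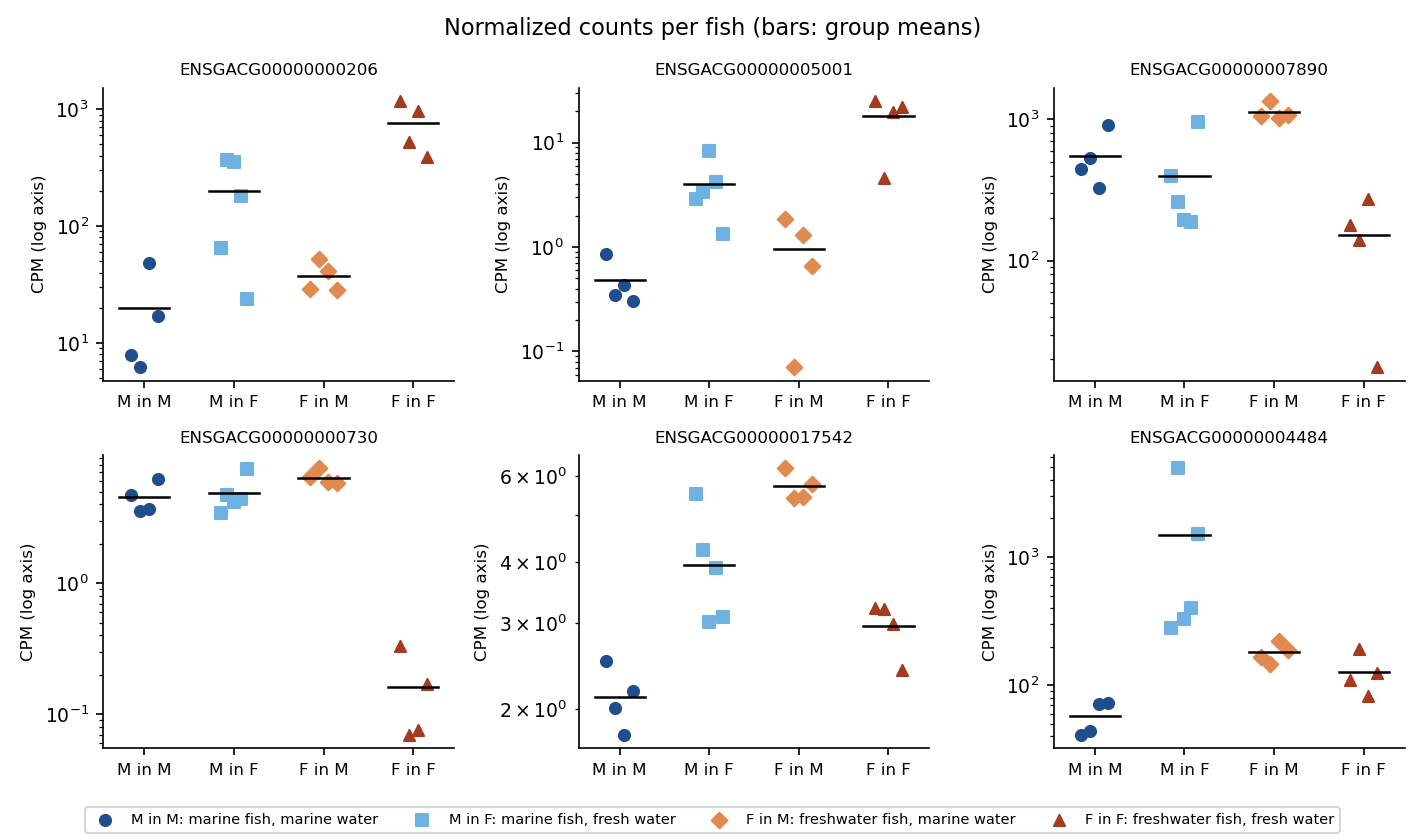
CPM on log axes for 6 named genes in each fish of the 4 groups, with horizontal bars at the group means. ENSGACG00000000206 and ENSGACG00000005001 have higher means in fresh water in both populations, ENSGACG00000000730 is at or below 0.33 CPM only in freshwater fish kept in fresh water, and ENSGACG00000004484 spans 277 to 4920 CPM among moved marine fish.

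Whether the 2 populations responded alike to water was asked in several ways, and the answers differed between all genes and the genes called. Across all 18238 genes the changes with fresh water had almost no relation between marine and freshwater fish (Pearson r = 0.04, Spearman rho = -0.07, covariance 0.01). The comparison shares no library and treats genes, which are not independent replicates, as points. Fresh against marine water is moved against kept in marine fish, but kept against moved in freshwater fish. A response to being moved that both populations share would lower r, so r cannot exclude a shared effect of water. Among the 137 genes called in freshwater fish r was 0.65, and among the 524 called in marine fish it was 0.26. Genes chosen for large changes on 1 axis can raise r by that choice. These values were not computed for other splits and cannot be set directly against 0.04. Of the 115 genes higher in fresh water in freshwater fish, 105 were also higher in fresh water in marine fish, and of the 22 lower genes 15 were also lower, 87.6% together against 46.2% of all genes. Such shares were not rare when the 9 marine fish were divided otherwise: 18 of 100 divisions, the real one included, were as extreme in either direction, 9 of them with the same sign. The other divisions had the same sign for a median of 56 and at most 131 of the 137 genes. All 9 divisions as extreme with the same sign held moved marine fish 1, 2 and 3 together, so most are near the real one. Read from the genes called in marine fish, 316 of 524 (60.3%) had the same sign in freshwater fish. Called in both populations were 45 genes, 43 higher and 1 lower in fresh water in both and 1 opposite, where independent lists of these sizes would share 1.7 and 0.3. Both lists share each gene's estimate of spread, because all groups were fitted together. Some excess over independent lists can therefore arise without a shared response. A shared spread has no direction and would add opposite genes as readily. Of the 45, 1 was opposite, which argues against spread as the source of the shared direction. The divisions above, in which shared signs were not rare, still limit this agreement. ENSGACG00000000206 and ENSGACG00000005001 are among the 43, with log2 changes in marine fish of 3.31 (SE 0.75, edgeR adjusted p = 0.032) and 3.14 (SE 0.76, edgeR adjusted p = 0.039). ENSGACG00000000206 was at 64.4 to 366 CPM in moved marine fish 1 to 4. In moved marine fish 5 it was at 23.6 CPM, within the range of kept marine fish (6.19 to 48.5 CPM). Adjusted over the list alone, 77 of the 137 genes passed in marine fish in the same direction and 1 in the opposite direction. That list came from the freshwater fish of the same study, not from before the data were examined, and all but the correlation across all genes were computed after the data had been seen. The overlap of 44 with the same direction fell to 0 wherever the marine response fell to 0, and was 91 without moved marine fish 5 and 106 with DESeq2.

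**Figure D3:**
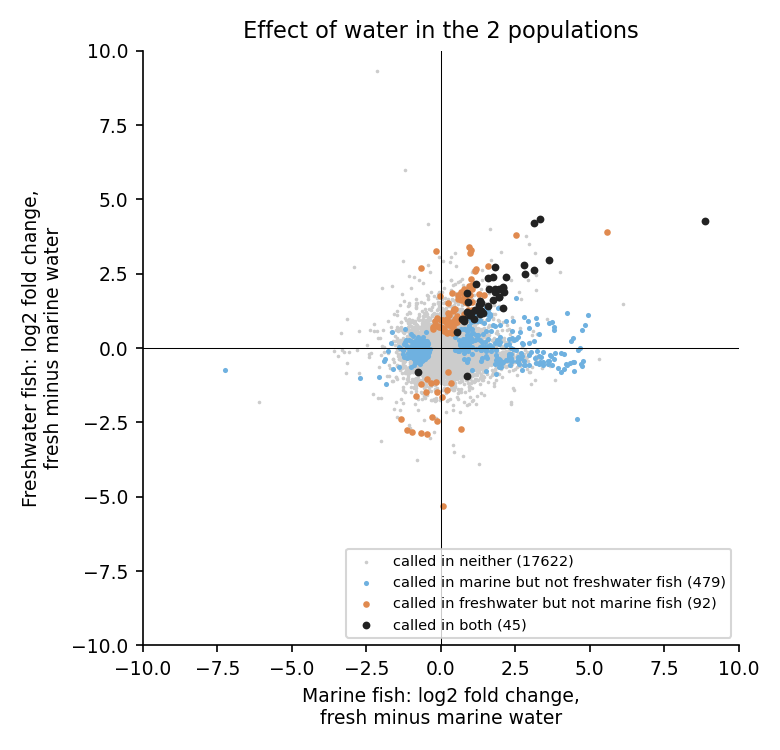
Log2 fold change of fresh over marine water in marine fish (horizontal) and in freshwater fish (vertical) for 18238 genes, coloured by the population in which a gene had an edgeR adjusted p below 0.05. The 45 genes called in both populations lie mostly at the upper right, while the 479 called in marine but not freshwater fish spread along the horizontal axis.

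Whether the effect of water differed between the populations was tested as an interaction, and 2 genes passed. In this design the interaction also equals kept minus moved fish, added over both populations. A response to being moved that both populations share therefore cannot be told apart from it. For ENSGACG00000000730, fresh water left marine fish at 4.84 ± 1.55 CPM (SD, n = 5) against 4.54 ± 1.21 CPM in marine water (n = 4), while in freshwater fish it was 0.161 ± 0.121 CPM in fresh and 6.41 ± 0.799 CPM in marine water (n = 4 each). The difference between these effects was -5.39 log2 units (SE 0.47, edgeR adjusted p = 1.9e-05), and it passed in 28 of 28 alternatives. ENSGACG00000017542 was higher away from the water of origin in both populations: 3.95 ± 1.02 against 2.12 ± 0.311 CPM in marine fish, and 5.72 ± 0.374 against 2.95 ± 0.383 CPM in freshwater fish. Its interaction was -1.83 log2 units (SE 0.28, edgeR adjusted p = 0.046) and passed in 10 of 28 alternatives. At an unadjusted p below 0.05 there were 3141 genes, DESeq2 called 241 and limma voom 8, and without moved marine fish 1 edgeR called 24. On simulated counts the interaction test recovered 45.5% of 4-fold and 6% of 2-fold differences, so most moderate differences between the populations would not be detectable here. The counts of 524 and 137 do not rank the populations: the order turned with limma voom (244 in marine and 627 in freshwater fish) and when only the groups compared were fitted (0 and 254).

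Freshwater and marine fish were compared in the same water, with the population moved from its own water differing between the 2 waters. In fresh water (4 kept freshwater and 5 moved marine fish), 1487 genes were higher and 1291 lower in freshwater fish, and among changes over 4-fold 82 were higher and 372 lower. This surplus of lower genes was not seen in marine water (138 higher and 118 lower) or with each population in its own water (227 and 126), which hold no moved marine fish. The lower genes include ENSGACG00000000068 and ENSGACG00000004484 (log2 differences -4.29 and -3.56, edgeR adjusted p = 0.0096 and 0.0061). Both were highest in moved marine fish 2, at 581 and 4920 CPM. How much of the surplus comes from the moved marine fish was not tested. Which direction held more of the genes also depended on the analysis: 53.5% were higher here, 60.1% with limma voom, 49.7% at equal depth, 45.6% with DESeq2, 45.1% with upper-quartile scaling, and 44.6% and 47.1% without moved marine fish 1 and 4. ENSGACG00000020323 was at 110 ± 87.5 CPM in freshwater fish (SD, n = 4) and 3.86 ± 2.64 CPM in marine fish (n = 5), a log2 difference of 4.77 (SE 0.61, edgeR adjusted p = 3.1e-04). ENSGACG00000012398 was at 212 ± 215 and 6.97 ± 5.42 CPM, a log2 difference of 4.92 (SE 1.32, edgeR adjusted p = 0.022), with 0.132 CPM in moved freshwater fish 1. ENSGACG00000007993 was at 0.0421 ± 0.0843 and 78.1 ± 50.4 CPM (log2 difference -10.76, SE 1.94, edgeR adjusted p = 0.0019), but it was also near absent in some marine fish, at 0.606 CPM in moved fish 2 and 0.428 and 0.0573 CPM in kept fish 2 and 3, against 70.4 to 123 CPM in the other marine fish. ENSGACG00000019490 was at 0.217 ± 0.0808 and 44.1 ± 34.2 CPM (log2 difference -7.65, SE 1.49, edgeR adjusted p = 0.0045), with 1.1 CPM in moved marine fish 5 and 0.254 CPM in kept marine fish 5. The 2778 genes are 15.2% of those tested, and 12% of tested genes had no overlap between the groups, where chance gives 1.59%. The count was 770 when only these 9 fish were fitted, 1835 with limma voom and 1560 at equal depth, and without kept freshwater fish 1, 2 or 4 it was 1812, 1622 and 1524.

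In marine water (4 moved freshwater and 4 kept marine fish), 2007 genes were higher and 2115 lower in freshwater fish, 22.6% of those tested, and the share that was higher (48.7%) ranged from 44.7% without kept marine fish 4 to 52.5% with upper-quartile scaling. ENSGACG00000001741 was at 172 ± 142 CPM in freshwater fish (SD, n = 4) and 3.09 ± 1.63 CPM in marine fish (n = 4), a log2 difference of 5.79 (SE 0.79, edgeR adjusted p = 3.2e-04), and ENSGACG00000015842 was at 34.1 ± 25.7 and 0.636 ± 0.262 CPM (5.75, SE 0.71, edgeR adjusted p = 1.9e-04). ENSGACG00000004618 was at 5.57 ± 7.56 and 220 ± 82.8 CPM, a log2 difference of -5.29 (SE 1.57, edgeR adjusted p = 0.023). Between the populations in fresh water it was not called (edgeR adjusted p = 0.086), with kept freshwater fish 5 at 110 CPM and moved marine fish 4 at 10.5 CPM. ENSGACG00000018668 was at 0.043 ± 0.0311 and 38.1 ± 62.7 CPM (log2 difference -9.57, SE 2.38, edgeR adjusted p = 0.0071), with 132 CPM in kept marine fish 3 and 0.214 CPM in kept marine fish 4, and kept freshwater fish were at 31.9 ± 36.9 CPM, so this gene did not separate the populations in general. No overlap was found for 27.2% of tested genes, where chance gives 2.86%. The count stayed within 1.5 times in every alternative, from 2751 at equal depth to 6131 with limma voom.

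Most of the population difference that was called in both waters had the same direction in both. Of 1170 genes called in fresh and in marine water, 749 were higher and 415 lower in freshwater fish in both, and 6 were opposite, where independent lists would share 163.6 and 149.7. These comparisons use different fish but share each gene's estimate of spread, which by itself can raise the overlap above that of independent lists. A shared spread has no direction and would raise opposite overlaps as readily. With 6 opposite genes of 1170, the values argue against it as the source of the shared direction. The 1170 genes had median differences of 0.81 and 0.92 log2 units in fresh and in marine water, and 86 differed more than 4-fold in both (44 higher and 42 lower). ENSGACG00000020323, ENSGACG00000001741 and ENSGACG00000015842 were higher in freshwater fish in both waters, with log2 differences between 3.89 and 5.79. The overlap of 1164 was 582 at equal depth and 510 when only the groups compared were fitted, and without kept freshwater fish 2 or 4 it was 752 and 698. Population, collection site and any batch of collection or sequencing cannot be told apart, because each population came from a single site and the labels give no batch.

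**Figure D4:**
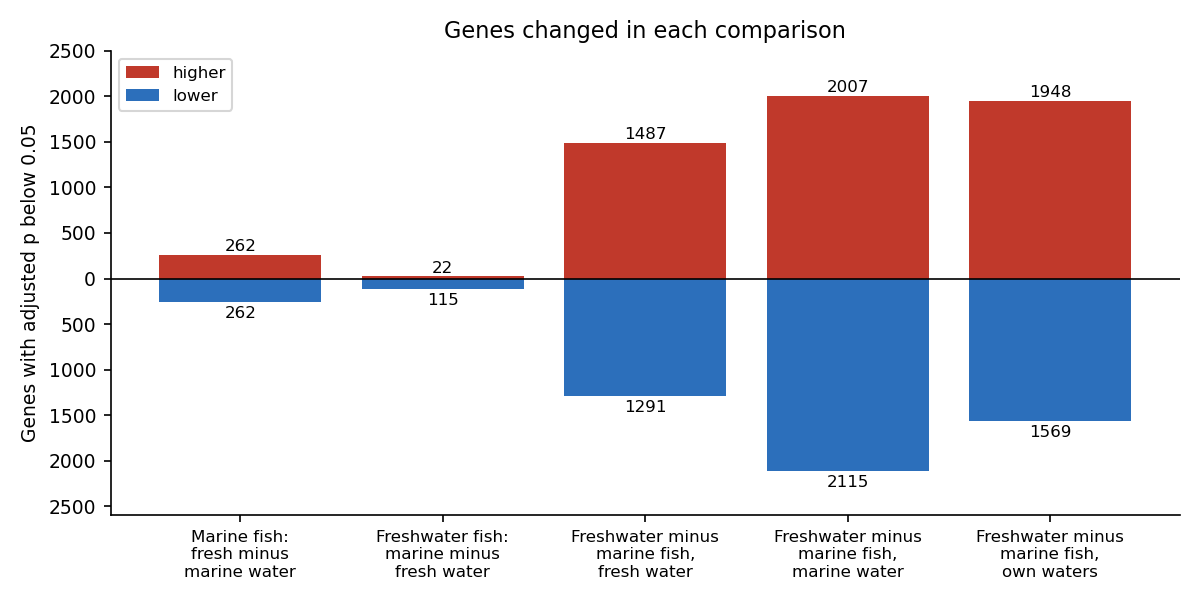
Number of genes with an edgeR adjusted p below 0.05 in each of 5 comparisons, higher above the zero line and lower below it. The comparisons of freshwater with marine fish hold 2778 to 4122 genes and the comparisons of water within a population 524 and 137.

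Freshwater and marine fish each in its own water differed in 3517 genes, 1948 higher and 1569 lower in freshwater fish. ENSGACG00000018949 was at 2990 ± 1370 CPM in freshwater fish (SD, n = 4) and 51.9 ± 61.3 CPM in marine fish (n = 4), a log2 difference of 5.84 (SE 0.99, edgeR adjusted p = 0.0011). ENSGACG00000019813 was at 48.4 ± 20.2 and 0.86 ± 0.631 CPM (log2 difference 5.81, SE 1.32, edgeR adjusted p = 0.0068), with 0.164 CPM in moved freshwater fish 1. ENSGACG00000019485 was at 2.56 ± 1.33 and 739 ± 673 CPM (log2 difference -8.18, SE 1.41, edgeR adjusted p = 0.0012), but kept marine fish 5 was at 4.16 CPM and moved marine fish 5 at 4.18 CPM, against 497 to 1600 CPM in the other kept marine fish and up to 3.79 CPM in kept freshwater fish. ENSGACG00000008840 had 0 counts in all 4 kept freshwater fish and 6.74 ± 6.61 CPM in kept marine fish, at least 232-fold lower when a floor of 3 counts over the group is used (edgeR adjusted p = 6.1e-04; at least 145-fold without kept marine fish 4), though kept marine fish 2 was at 0.0612 CPM. Here population and water change together, and ENSGACG00000018949 was also at 407 ± 342 CPM in marine fish moved to fresh water and 265 ± 110 CPM in freshwater fish moved to marine water. No overlap was found for 21.7% of tested genes, where chance gives 2.86%. The count was 2317 at equal depth, and without kept freshwater fish 2 or 4 it was 2267 and 2179.

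The response of marine fish to fresh water was also set against the difference between freshwater and marine fish in their own waters, to ask whether moved marine fish changed toward freshwater fish. Across 18238 genes r was 0.38 and the covariance 0.184, but both comparisons use the same 4 kept marine fish. Simulated groups with no effect gave a higher r, 0.52 on average (0.5 to 0.54 in 20 simulations), with a covariance of 0.078, which leaves a difference in covariance of 0.106. With the kept marine fish divided between the comparisons, r was 0.18 on average (0.07 to 0.29 over 6 divisions) and the covariance 0.102 (0.047 to 0.155). On genes called between the populations in both waters without the fish in question, a median position of 0 stands for the marine and 1 for the freshwater mean. Genes in which moved marine fish had reached the freshwater level are not called in fresh water and were left out. The position is thus weighted against finding a shift of moved marine fish. Moved marine fish were at 0.13 ± 0.1 (SD, n = 5) and kept marine fish at -0.03 ± 0.18 (n = 4), a difference of 0.16 that did not pass a two-sided exact permutation test (p = 0.135, Benjamini-Hochberg 0.27 over 2 tests). For freshwater fish, moved were at 0.98 ± 0.02 and kept at 0.92 ± 0.2 (n = 4 each, exact permutation p = 0.571).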

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

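All tests that weigh an explanation here were chosen, and their thresholds set, after the results had been seen, the counts of other splits included, except that the interaction, the pairwise counts and the correlation of the water responses were planned comparisons. Single fish stood apart from the rest of their group in 17 of 108 groups of values examined. Normally distributed values would give about 1 in 20 groups, or 5.4. Most groups were untransformed CPM of genes chosen for large changes, so 5.4 is likely a low reference. The values of a gene are linked across groups, so these are not 17 separate events.

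The share of counts in the 10 most abundant genes was 14.47% in kept marine fish 2 (12.51% to 12.78% in the others of its group), 19.4% in moved marine fish 2 (12.98% to 14.33%) and 12.88% in kept freshwater fish 1 (12.48% to 12.5%). ENSGACG00000000068 was at 7.5 CPM in kept marine fish 5 (5.14 to 5.41) and 581 CPM in moved marine fish 2 (9.2 to 169). ENSGACG00000004484 was at 4920 CPM in moved marine fish 2 (277 to 1520). ENSGACG00000007890 was at 956 CPM in moved marine fish 5 (188 to 398) and 1350 CPM in moved freshwater fish 2 (1020 to 1070). ENSGACG00000018949 was at 143 CPM in kept marine fish 4 (13.6 to 28), and ENSGACG00000020323 at 1.45 CPM in the same fish (2.75 to 2.94). ENSGACG00000007993 was at 1.38 CPM in moved freshwater fish 1 (0.141 to 0.263) and 0.169 CPM in kept freshwater fish 5 (0 in the others, a difference of 4 counts). ENSGACG00000001741 was at 385 CPM in moved freshwater fish 3 (95.8 to 108). ENSGACG00000018668 was at 132 CPM in kept marine fish 3 (0.214 to 15.2) and 31 CPM in moved marine fish 3 (0 to 8.59). ENSGACG00000004618 was at 16.9 CPM in moved freshwater fish 1 (1.61 to 1.9) and 110 CPM in kept freshwater fish 5 (0.33 to 0.732).

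The interaction test passed for ENSGACG00000000730 (-5.39 log2 units) and ENSGACG00000017542 (-1.83 log2 units). A water effect that differs between the populations and a shared response to being moved cannot be told apart by this test. ENSGACG00000017542 was higher in moved than in kept fish of both populations. ENSGACG00000000730 was called between waters in freshwater but not in marine fish. Of 100 drawn splits of the fish within each population (8820 are possible), 4 including the real one gave 2 or more interaction genes, and the highest other gave 1097. A split with so many more genes than the real 2 points to a structure among the fish that is not the water, so the small count is weak evidence by itself.

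The marine response to fresh water (524 genes) could come from depth or from a few fish. With all libraries thinned to the lowest total 242 genes were called, which argues against depth as the whole cause. Without moved marine fish 1 and 2, the farthest from their group, 105 genes were called, which cannot be told apart from a loss of power by fewer fish. Of 100 drawn splits of the 9 marine fish, 4 including the real one gave at least 524 genes, and the highest other gave 954 (kept marine fish 2, 3 and 5 with moved marine fish 1 and 3, against the rest), which points to structure among the marine fish besides the water. A response to fresh water, which the design names, stays open beside that structure.

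The population difference in both waters could come from depth or from sequence differences between the populations, and wrong labels could blur it. At equal depth 582 genes were called in both waters with the same direction, against 128.7 for independent lists. That reference is low, because the lists share each gene's estimate of spread. Spread has no direction, though, and at full depth 6 of 1170 genes called in both waters were opposite. The number of fish nearer the other population, on genes called without the fish, was 0. The count at equal depth argues against depth as the whole cause. A wrong population label would weaken the difference and not create it, so the 0 bears only on the labels. Loss of reads of 1 population to the reference used for alignment cannot be told apart from expression: 64.3% of the shared genes were higher in freshwater fish, but scaling centres the changes and the reference is not given. The real splits gave 3517 genes (own waters, 1 of 35 splits as large, highest other 1303), 4122 (marine water, 1 of 35, highest other 735) and 2778 (fresh water, 1 of 100, highest other 1968), so chance division of these fish is an unlikely source of the 3 counts. An inherited population difference, an effect of site and a batch stay open and untested.

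The counts with a shared divisor could come from both mates of a read pair being counted, or from a fixed number of counts per read set by the gene, such as by the number of transcripts. Divisors of 3 or another odd number occurred in 881 genes, which argues against mates alone. Of genes with a divisor in the marine fish, 97.2% had the same divisor in the freshwater fish, consistent with a number fixed per gene. No biological explanation was tested. Transcript numbers per gene were not used here.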

How the results depend on the processing

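The overlaps, sign shares, list-alone count, correlation among called genes, thinned libraries, divided counts, lower bounds without single fish and fits without moved marine fish 1 and 2 together were chosen after seeing the data; the other alternatives were planned. Of 633 values of named genes under alternatives, 557 stayed past the threshold, 76 did not and 0 changed sign. Genes named from pairwise comparisons were chosen for large changes without overlap between the groups. A change of sign was therefore hardly possible for them, and its absence is no sign of robustness. Division by the shared divisor, DESeq2 size factors and upper-quartile scaling moved no count by over 1.5 times. The tests of gene lists were not run, because no ID could be matched to a name, and the interaction has no fit of only the groups compared because it uses all 4. At equal depth fewer genes were called in each pairwise comparison. The cause of the other changes was not tested.

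For the marine response (524 genes), DESeq2 gave 1733, limma voom 244, only the groups compared 0 (3107 at an unadjusted p below 0.05), equal depth 242, without moved marine fish 1 and 2 105, and leaving out each fish in turn 0 to 1221. For the freshwater response (137), DESeq2 gave 347, limma voom 627, only the groups compared 254, equal depth 71, and each fish left out 37 to 180. For the populations in their own waters (3517), equal depth gave 2317 and each fish left out 2179 to 4091. For the populations in fresh water (2778), limma voom gave 1835, only the groups compared 770, equal depth 1560, and each fish left out 1524 to 3002. In marine water (4122) no alternative moved the count by over 1.5 times. For the interaction (2), no low-count filter, robust edgeR and equal depth each gave 1, DESeq2 241, limma voom 8, without moved marine fish 1 and 2 26, and each fish left out 1 to 24. For the water overlap (44), DESeq2 gave 106, only the groups compared 0, equal depth 23, without moved marine fish 1 and 2 18, and each fish left out 0 to 91. For the population overlap (1164), only the groups compared gave 510, equal depth 582, and each fish left out 698 to 1193. The correlation of the water responses (0.04) was 0.65 among genes called in freshwater fish, 0.26 among those called in marine fish, and -0.02 to 0.09 with each fish left out, and that of the marine response and the population difference (0.38) was 0.44 with the stricter filter and 0.32 to 0.47. The same-sign share (87.6%) was 85.4% with limma voom, 84.7% without moved marine fish 1 and 2, and 83.2% to 90.5% with each fish left out. The list-alone count (77) stayed within 1.5 times in all alternatives.

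With the fish number as a replicate block, edgeR called 0 genes in the marine response (3721 at an unadjusted p below 0.05), 98 in the freshwater response and 1 in the interaction. The water overlap was 0, the correlation of the water responses -0.07 and the same-sign share 85.4%. Deviations of 21 same-numbered pairs, most of them between populations, correlated from -0.27 to 0.23 (median 0.02, 5 over 0.1). For kept and moved marine fish 2, 3, 4 and 5 the correlations were -0.19, 0.19, 0.19 and 0.23, so not every pair was positive. Of 17 fish, 6 correlated best with their own number. Whether the numbers pair the marine fish cannot be settled by these values.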

Other observations

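All tests in this part that compare the water responses by called genes, and all counts of other splits, were chosen after the results had been seen, the list-alone count after the 524 genes had been seen to fall to 0 in some fits; the correlation across all genes and the count for freshwater fish were planned. The freshwater response of 137 genes was given by 1 of 35 splits of the 8 freshwater fish, the real one, and the highest other gave 7, so chance division of these fish is an unlikely source.

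Genes that freshwater fish lowered in marine water may respond to salinity in marine fish too. The 115 genes had a median log2 difference between fresh and marine water of 1.5 in freshwater and 0.88 in marine fish, and 71 passed in marine fish adjusted over the list alone, with 0 in the opposite direction. The 22 genes with the reverse direction had medians of -1.55 and -0.32, and 6 passed with 1 opposite. The genes were chosen on the freshwater values, which enlarges those medians. The sizes therefore do not show a weaker response in marine fish. The tests of this idea did not all go the same way. Of 100 drawn splits of the marine fish, 3 including the real one gave at least 77 list-alone genes in either direction, the highest other being 93, and 2 did so in the same direction. The others kept moved marine fish 1 to 4 together and set moved marine fish 5 with kept fish (78 and 93 genes). They are thus near the real split, and a count this high did not need moved marine fish 5 on the moved side. For the 120 of 137 genes with the same sign, 18 of 100 splits had as many genes of the same or of the opposite sign (9 of them the same sign, the real one included), and the highest other gave 131, so chance division is not excluded for the sign share. For the correlation across all genes, 61 of 100 splits within populations were as far from 0 as 0.04 in either direction, the highest other was 0.26, and chance is not excluded. The overlap of 44 was reached by 1 of 100 such splits, the real one, with 0 as the highest other, but this says nothing about sharing: other splits of the freshwater fish called at most 7 genes, so the overlap could not come near 44. A shared response therefore remains a hypothesis about a small set of genes. For the transcriptome the correlation cannot decide, because a shared response to being moved would lower it.

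A shift of moved marine fish toward freshwater fish was tested with the position on genes called between the populations without the fish in question. The difference of mean position was 0.16 (exact permutation p = 0.135), which neither excludes nor establishes such a shift. Genes had to differ between the populations in fresh water as well, so those in which moved marine fish shifted fully were left out. The test was therefore weighted against a shift. Kept marine fish 5 was at 0.23 and kept freshwater fish 5 at 0.67, each the nearest of its kept group to the other population.

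Exact permutation tests of the spread of fish around their group (SD of log2 deviations at equal depth, 3 tests, two-sided) passed for none. The mean was 0.694 in 9 marine and 0.655 in 8 freshwater fish (exact p = 0.248, Benjamini-Hochberg 0.372). It was 0.714 in 5 moved and 0.669 in 4 kept marine fish (exact p = 0.437, Benjamini-Hochberg 0.437), and 0.622 in 4 moved and 0.688 in 4 kept freshwater fish (exact p = 0.0571, Benjamini-Hochberg 0.171).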
